A study of Homo sapiens with 9 samples.

How the data were processed

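Chromatin immunoprecipitation with sequencing (ChIP-seq) was performed on K562 cells, a human erythroleukaemia line, after 48 h with hemin, which induces erythroid maturation. All cells stably expressed BirA, a bacterial biotin ligase. In addition, 1 group carried zfp148 (also called ZBP-89) and 1 group carried zfp281 (ZBP-99) with a 23-amino-acid biotin acceptor motif at the amino terminus, here called bio-zfp148 and bio-zfp281 cells. Per the labels' protocols, cells were fixed with 1% formaldehyde for 10 min, chromatin was sonicated, and biotinylated protein with its DNA was recovered on streptavidin beads. The labels name 6 ChIP libraries, 2 each for BirA alone, bio-zfp148 and bio-zfp281, and 3 input libraries, 1 per group. The input libraries entered only through the authors' peak calls. Nothing in the labels says that the replicates came from separate cultures, so their spread may be technical. The p-values come from random placements, from permutations of chromosomes and from Fisher's exact test on counts of sites, and none measures the spread between cultures.

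Per the submitters' processing notes, reads were mapped with Bowtie 1.0.0 to hg19 and peaks were called with MACS 1.4. The file headers name MACS 1.4.0rc2, with a p cutoff of 1e-05, a model fold of 10 to 30, a band width of 300 bp, an effective genome size of 2.70e+09 and tags of 50 bp. Peaks were called by the authors on each library and again on both replicates of a group joined, giving 9 lists, each against an input. Per the file headers, the smaller data set was scaled up to the larger one, and the local background was taken over 1000 and 10000 bp. Per the file headers, at most 1 tag per position was kept in the 4 single bio-zfp148 and bio-zfp281 libraries and BirA replicate 2, and at most 2 in BirA replicate 1 and the pooled lists. The pooled bio-zfp148 and bio-zfp281 lists therefore rest on 1.58 and 1.65 times the filtered tags of their replicates added together.

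Each deposited list gives, per peak, a tag count, the −log10 p multiplied by 10 (here the p scale), the fold enrichment over the local background as a ratio, and a false discovery rate (FDR) as a percentage, all computed by the authors. The tag count was deposited without normalisation. The fold enrichment and the p scale were used only to describe, rank or filter peaks within a list. Peak lists hold no value at places that were not called, so no count model was fitted and no difference in signal was tested.

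A site of a protein was defined as a peak of its pooled list that overlapped (by at least 1 bp) a peak in both of its replicates and no peak of any of the 3 BirA lists. Overlap shares were given with exact (Clopper-Pearson) 95% binomial intervals, which cover counting error only. They were compared with 1000 random placements of the peaks on their own chromosome, between position 1 and the highest peak end in any list, and placements of sites kept out of BirA peaks. The test was one-sided, and the smallest p it can give is 0.001. A local control shifted each site by 5 to 50 kb in 100 placements, for which the smallest p is 0.01. Tag counts and sites per Mb were given with exact Poisson intervals. Relations across chromosomes used Pearson's r and Spearman's rho with 100000 permutations, and 5 such relations were adjusted together by the Benjamini-Hochberg method. The share of each protein's sites on each of 23 chromosomes was compared by Fisher's exact test, two-sided, with the same adjustment. The site definition, the comparison with random placements and the rule for named sites were set before the data were examined. The local control and the comparisons by strength, of summit distances and across or between chromosomes were chosen after seeing the data. That rule takes the 10 sites with the highest fold enrichment among shared sites (by the worse of their ranks in the 2 lists) and among the sites of each protein alone.

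The overlap test was checked on simulated lists. These held 4885 intervals with the widths of the bio-zfp148 sites, placed at random, and shifted copies of some were planted in the other list. Of the 4885, 20.3%, 40.2% and 60.2% were recovered as shared where 20%, 40% and 60% had been planted, and 0.184% where none had been. Of 40 unrelated lists of 4885 places, 1 reached p at or under 0.05, and of 40 unrelated lists of 3462 places, 2 did. The unrelated lists were placed at random as in the test itself. The check therefore covers the counting and does not show how the test behaves on real sites, which cluster. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9 was used.

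Alternatives were an overlap of at least 50% of the shorter peak, summits within 200 bp, a minimum of 100 on the p scale, a minimum fold enrichment of 10, a maximum FDR of 5%, other uses of the BirA lists, no replicate support, the strongest 5000 peaks, a replicate block and each replicate left out in turn. Coordinates are those of the lists on hg19, counted from 1. The gene table at hand describes GRCh38.p14, so no hg19 genome or annotation was used. The promoter shares, gene lists, sequence elements and genes planned by name were therefore not analysed here, and places are named by coordinates alone.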

Results

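Streptavidin ChIP-seq was used to map where zfp148 and zfp281, a pair of related zinc finger proteins known to bind G-rich DNA, sat on chromatin in hemin-treated K562 cells. A biotin tag was chosen over antibodies because antibodies to these proteins might cross-react. Cells with the ligase BirA but no tagged protein served as the control. The 6 ChIP libraries formed 3 groups of 2. After duplicate removal, replicates 1 and 2 held 810565 and 1497503 tags in bio-zfp148, 1570283 and 906911 in bio-zfp281, and 15956688 and 1080363 in BirA. Duplicate removal kept only 14.2% and 15.7% of the tags in bio-zfp148, 16.7% and 11.7% in bio-zfp281, and 34.5% and 10.5% in BirA. Depth below means the tags left after it. The inputs held 6194106 of 9422101 tags for BirA, 6620480 of 9635684 for bio-zfp148 and 11628663 of 13540486 for bio-zfp281. The authors called 16421 and 18603 peaks in bio-zfp148 replicates 1 and 2, 28813 and 9895 in bio-zfp281 replicates 1 and 2, and 66002 and 7819 in BirA replicates 1 and 2. The pooled lists held 44202 bio-zfp148, 68319 bio-zfp281 and 56341 BirA peaks. Peaks were called on few tags. The median peak held 10 tags in both pooled lists of tagged protein, for which counting error alone allows 4.80 to 18.4.

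The replicates of each tagged protein shared more of their peaks than the BirA replicates did. Of the bio-zfp281 replicate 2 peaks, 73.0% (95% interval 72.1 to 73.9%) overlapped a replicate 1 peak, against 1.52% in random placements. Of the bio-zfp148 replicate 1 peaks, 52.9% (52.2 to 53.7%) overlapped a replicate 2 peak, against 0.896% in random placements. In BirA cells, 24.1% (23.2 to 25.1%) of the replicate 2 peaks overlapped one of the far more numerous replicate 1 peaks, against 2.52% by placement. In the other direction, 24.99% of the longer bio-zfp281 replicate 1 list, 46.5% of bio-zfp148 replicate 2 and 2.79% of BirA replicate 1 met the other replicate. All 3 shares of the shorter lists lay above every one of 1000 placements (one-sided permutation p = 0.001, the smallest possible). Across matched peaks, which are not independent, the authors' fold enrichments of the replicates followed each other with a Spearman rho of 0.766 in bio-zfp148, 0.756 in bio-zfp281 and 0.462 in BirA. Among the strongest 5000 peaks of each list the shares were 57.1% for bio-zfp281, 61.3% for bio-zfp148 and 9.16% for BirA. The BirA share fell to 11.2% at a p scale of at least 100 and to 16.1% for summits within 200 bp. Overlap as high as between replicates was not particular to 1 protein. The longer bio-zfp281 replicate 1 list was met by 57.2% of bio-zfp148 replicate 1 peaks and 60.8% of bio-zfp148 replicate 2 peaks. The shorter bio-zfp281 replicate 2 list was met by 33.0% and 32.8%. Of the bio-zfp281 replicate 2 peaks, 54.5% and 61.8% met bio-zfp148 replicates 1 and 2.

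**Figure D1:**
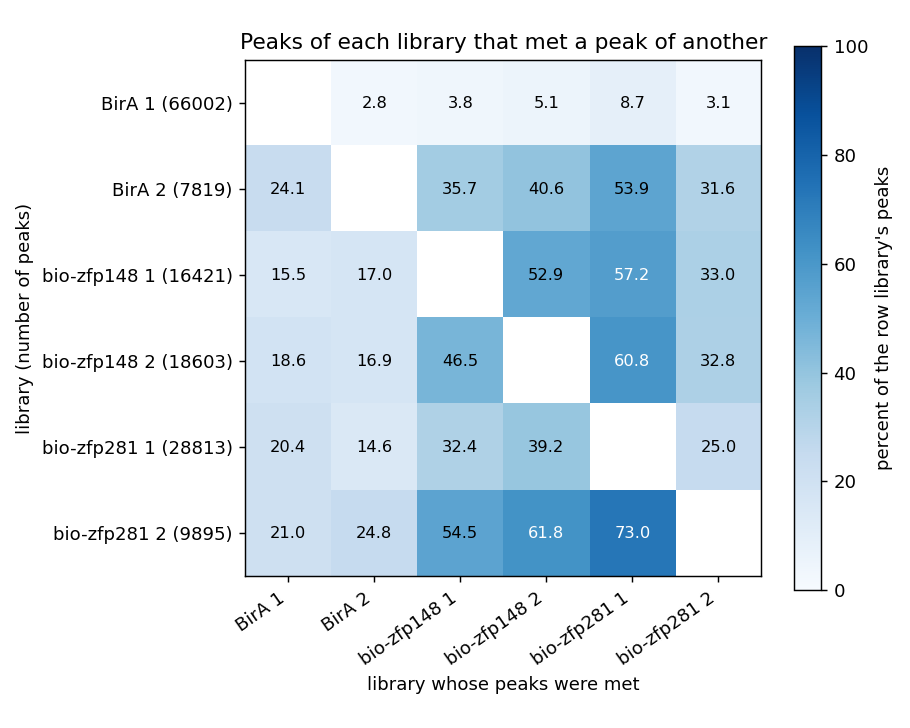
Percent of the peaks of each library (rows, with the number of peaks; 1 and 2 are replicates) that overlapped a peak of each other library (columns) by at least 1 bp. BirA replicate 2 met bio-zfp281 replicate 1 in 53.9% of its peaks and BirA replicate 1 in 24.1%.

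Cells without a tagged protein gave peaks at many of the same places. A BirA peak overlapped 10183 of the 44202 pooled bio-zfp148 peaks, or 23.0% (22.6 to 23.4%), against 3.29% in random placements. It overlapped 15330 of the 68319 pooled bio-zfp281 peaks, or 22.4% (22.1 to 22.8%), against 3.39% (one-sided permutation p = 0.001 for both, the smallest possible). The overlap was greatest at the strongest peaks. In the strongest 10% by p, 48.8% (47.4 to 50.3%) of bio-zfp148 peaks and 50.4% (49.2 to 51.6%) of bio-zfp281 peaks met a BirA peak, against 19.7% and 15.7% of the weakest 10%. BirA replicate 2 alone met 34.6% and 31.1% of the strongest 10% of peaks, and the deeper replicate 1 met 19.2% and 26.1%. The control lists differed in their FDRs, which do not rank them by quality. In BirA replicate 1 and the pooled BirA list the ChIP held more tags than the input, so the input was scaled up. In every other list the ChIP was scaled up, and FDRs of lists scaled in different directions may not be comparable. No peak of BirA replicate 1 or of the pooled BirA list had an FDR of 5% or less (lowest 31.6% and 38.6%), while 94.4% of the BirA replicate 2 peaks and 88.5% and 84.8% of the pooled bio-zfp148 and bio-zfp281 peaks did. The share depended on the BirA library used: replicate 2 alone met 9.07% of bio-zfp148 and 7.55% of bio-zfp281 peaks, replicate 1 alone 14.3% and 14.7%, and peaks found in both replicates 2.89% and 2.48%. Random placements gave 0.350% and 0.365% for replicate 2, and 2.59% and 2.65% for the far longer replicate 1 list. Replicate 2 thus lay further above chance, 25.9 and 20.7 times against 5.50 and 5.56 times. A fold enrichment of at least 10 lowered the share met by any BirA list to 5.95% and 7.51%, and a p scale of at least 100 to 15.5% and 13.7%. Among the strongest 5000 peaks of each list it was 27.6% and 31.3%.

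**Figure D2:**
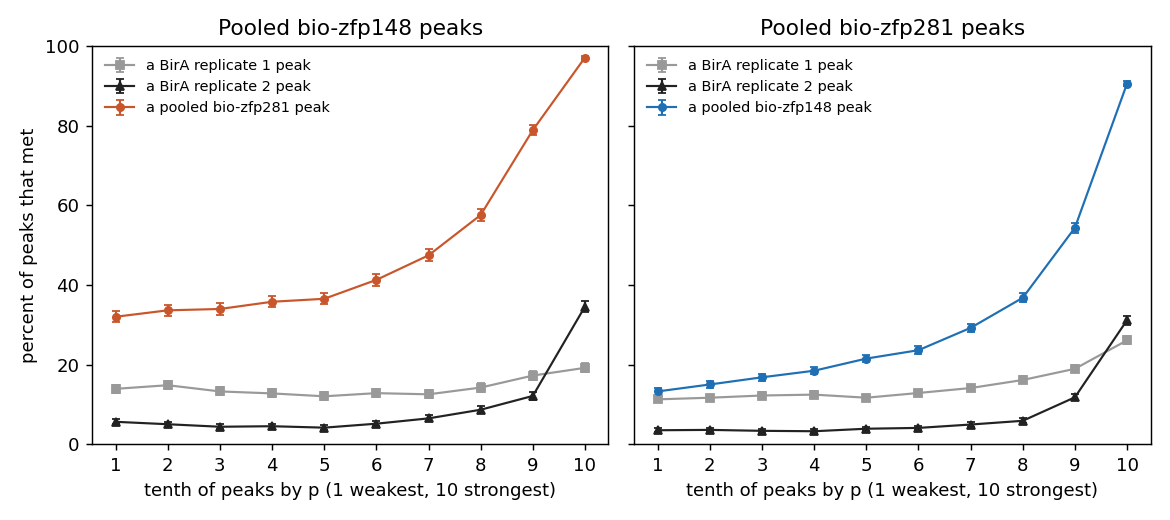
Percent of pooled bio-zfp148 peaks (left) and pooled bio-zfp281 peaks (right) that overlapped a BirA replicate 1 peak (grey), a BirA replicate 2 peak (black) or a pooled peak of the other protein (coloured), in 10 equal parts of the list ordered by p; bars are exact 95% binomial intervals. Overlap with BirA replicate 2 rose to 34.6% and 31.1% in the strongest part, and overlap with the other protein to 97.1% and 90.5%.

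After the BirA peaks were set aside, 4885 bio-zfp148 sites and 3462 bio-zfp281 sites remained. Support in both replicates was the larger filter. Of the pooled bio-zfp148 peaks, 8520 (19.3%) met a peak in both replicates and 20390 (46.1%) met a peak in neither. Of the pooled bio-zfp281 peaks, 7066 (10.3%) met both and 38187 (55.9%) met neither. A BirA peak then removed 3635 (42.7%) of the supported bio-zfp148 peaks and 3604 (51.0%) of the supported bio-zfp281 peaks. The sites had a median width of 672 bp and 28 tags for bio-zfp148, and of 773 bp and 35 tags for bio-zfp281. Their median fold enrichment, which is scaled within each list, was 23.6 and 15.2. The counts depended on these filters. A minimum fold enrichment of 10 in every list left 2043 and 480 sites, removing no BirA peak gave 8520 and 7066, removing only those found in both BirA replicates 7922 and 6397, and asking for no replicate support 34019 and 52989. With BirA replicate 2 left out there were 5272 bio-zfp281 sites. Taking the peaks of 1 library for the group gave 12371 bio-zfp148 sites without replicate 1, 11351 without replicate 2, 5762 bio-zfp281 sites without replicate 1 and 19144 without replicate 2.

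The sites of both proteins coincided far more often than chance gives. A bio-zfp281 site overlapped 2017 of the 4885 bio-zfp148 sites, or 41.3% (39.9 to 42.7%), and a bio-zfp148 site overlapped 1997 of the 3462 bio-zfp281 sites, or 57.7% (56.0 to 59.3%). Random placements outside BirA peaks gave 0.255% and 0.353% (one-sided permutation p = 0.001, the smallest possible). Shifts of 5 to 50 kb, which keep a site in its own neighbourhood, gave 1.01% and 1.36%. Both sets had been cleared of the same BirA peaks, and random placements do not hold the true occupancy of either protein. Within the 72930 places called in either pooled list outside BirA peaks, 1977 held a site of both, where independent lists of these sizes would give 228. The value of 228 takes all places as equally likely to be sites. Support in both replicates rose from 0.679% of the weakest 10% of pooled bio-zfp148 peaks to 94.8% of the strongest, and from 0.234% to 70.9% for bio-zfp281. If the same places are strong in both lists, 228 is too low as a chance level. With no BirA peaks removed, more were shared, 53.3% of 8520 bio-zfp148 and 63.4% of 7066 bio-zfp281 peaks. Sharing was thus higher when places that BirA cells also gave were kept. With bio-zfp148 filtered by BirA replicate 1 alone and bio-zfp281 by BirA replicate 2 alone, 32.4% of bio-zfp148 sites were shared, and 35.4% with the BirA replicates exchanged. The share moved with bio-zfp281 replicate 2. When it was left out, 76.1% of bio-zfp148 sites and 3829 of a far longer list of 19144 bio-zfp281 sites were shared. At a fold enrichment of at least 10, 292 of 2043 bio-zfp148 sites (14.3%) and 287 of only 480 bio-zfp281 sites (59.8%) were shared. For bio-zfp148 the share was 21.5% and 20.7% without bio-zfp148 replicate 1 or 2, and 25.8% for bio-zfp281 with no replicate support asked.

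Sharing rose with strength in both proteins. Of the 20% of bio-zfp148 sites with the lowest fold enrichment, 28.7% (25.8 to 31.6%) met a bio-zfp281 site, and of the 20% with the highest, 56.9% (53.74 to 60.04%) did. For bio-zfp281 sites the share went from 37.2% (33.6 to 40.9%) to 75.04% (71.6 to 78.2%). Overlap with any pooled peak of the other protein rose less, from 83.8% to 93.4% for bio-zfp148 and from 71.1% to 94.5% for bio-zfp281. A shared site needs a call in both replicates of the other protein, so easier detection of strong places cannot be told apart from occupancy here. The median fold enrichment was 28.4 at shared and 20.8 at other bio-zfp148 sites, and 18.5 at shared and 12.0 at other bio-zfp281 sites. Across the 2017 shared pairs the fold enrichments of the proteins followed each other with a Spearman rho of 0.555, across regions that are not independent replicates.

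**Figure D3:**
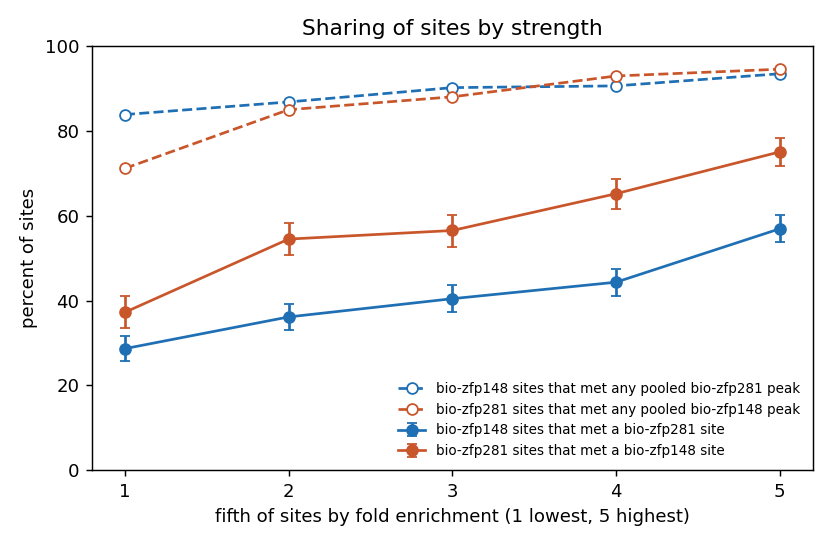
Percent of bio-zfp148 (blue) and bio-zfp281 (orange) sites that overlapped a site of the other protein (solid lines, with exact 95% binomial intervals) or any pooled peak of the other protein (dashed lines), in 5 equal parts of the sites ordered by fold enrichment. The solid lines rose from 28.7% to 56.9% for bio-zfp148 and from 37.2% to 75.04% for bio-zfp281.

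The 10 strongest shared sites were chosen by pooled fold enrichment, and a shared site is called in both replicates of each protein by definition. Some rested on few tags in a single library. The site at chromosome 10:93057617-93058439 held 5 tags in bio-zfp281 replicate 2, the fewest of any peak in that list. The strongest lay at chromosome 11:118768697-118769202, with a fold enrichment of 251 on 69 tags in the pooled bio-zfp148 list. The matching bio-zfp281 peak at chromosome 11:118768447-118769148 had a fold enrichment of 210 on 91 tags, and the summits were at 118768906 and 118768923. In the single libraries its fold enrichment was 172 and 216 in bio-zfp148 and 81.7 and 34.3 in bio-zfp281. The next lay at chromosome 3:160603462-160604165, with a fold enrichment of 220 for bio-zfp148 and 203 for bio-zfp281. Chromosome 13:100632817-100633816 followed with 189 and 144, and chromosome 20:23618357-23619354 with 219 and 130. Over the 10 places the pooled fold enrichment ranged from 133 to 251 for bio-zfp148 and from 82.9 to 210 for bio-zfp281.

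Most sites outside the shared set still held a peak of the other protein, 2329 of 2868 (81.2%) for bio-zfp148 and 991 of 1465 (67.6%) for bio-zfp281. In a comparison chosen after seeing the data, over all sites, shared ones included, 4346 of the bio-zfp148 sites (89.0%, 88.1 to 89.8%) overlapped a pooled bio-zfp281 peak, where shifts of 5 to 50 kb gave 8.62%. Of all bio-zfp281 sites, 2988 (86.3%, 85.1 to 87.4%) overlapped a pooled bio-zfp148 peak, where shifts gave 6.02%. Among the 2868 bio-zfp148 sites that were not shared, 1685 (58.8%) met a bio-zfp281 peak in the pooled list and replicate 1 but not in replicate 2, the shallower library. The 10 strongest of them, with fold enrichments of 141 to 227, all had such a peak, with a bio-zfp281 fold enrichment of 7.97 to 44.0. They included chromosome 6:164134205-164134673, with a fold enrichment of 227 for bio-zfp148 and 23.7 for bio-zfp281, and chromosome 1:1105677-1106102, with 185 and 22.9. A pooled bio-zfp148 peak lay at 8 of the 10 strongest bio-zfp281 sites outside the shared set. Among these was chromosome 20:60943508-60944291, with a fold enrichment of 273 for bio-zfp281 and 100 for bio-zfp148, where the bio-zfp148 peak also met a BirA peak. Chromosome 20:61317454-61318196 had a fold enrichment of 135 on 51 tags for bio-zfp281 and no bio-zfp148 peak in any of the 3 lists.

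Where the sites were shared, the summits of the proteins lay about as close together as those of replicates. The summits of overlapping sites lay a median of 35 bp apart (quartiles 15 and 74 bp), and 81.7% were within 100 bp. The summits of the replicates at shared sites lay a median of 42 bp apart in bio-zfp148 and 45 bp apart in bio-zfp281. Across the 4 pairs of single libraries of different proteins, the medians were 39, 47, 47 and 48 bp. The distances between the proteins and those between replicates of 1 protein thus covered nearly the same range. Pooled bio-zfp148 and BirA peaks that overlapped had summits a median of 133 bp apart, and pooled bio-zfp281 and BirA peaks 130 bp. Against BirA replicate 2, the control list with most peaks at a low FDR, the medians were 60 bp for bio-zfp148 and 65 bp for bio-zfp281, nearer to those between single libraries. The BirA comparisons took all overlapping pooled peaks, with or without replicate support, and not sites alone. Their distances are therefore not a like-for-like contrast with those at shared sites.

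**Figure D4:**
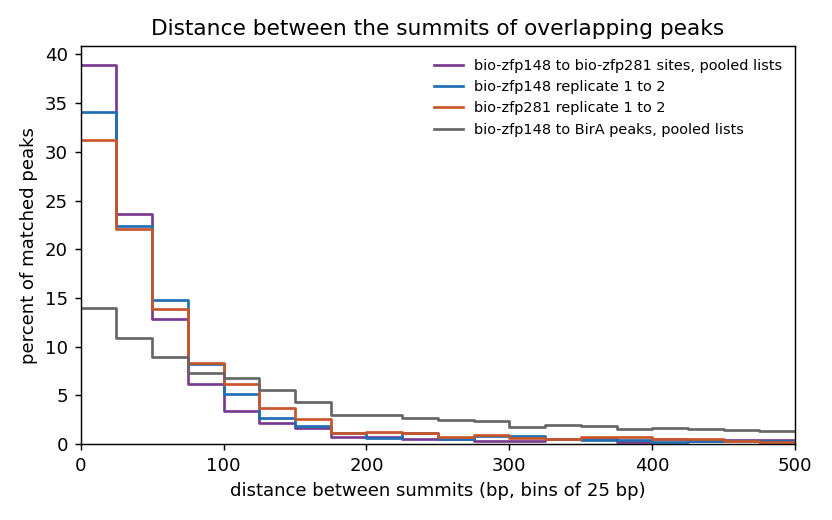
Distance between the summits of overlapping peaks (x axis, in bins of 25 bp) as a percentage of matched peaks (y axis), for bio-zfp148 against bio-zfp281 sites, for the replicates of each protein at shared sites, and for pooled bio-zfp148 against pooled BirA peaks. The median was 35 bp between the proteins and 133 bp against pooled BirA peaks, and it was 60 bp against BirA replicate 2 (not drawn). The BirA values cover all overlapping pooled peaks, with or without replicate support.

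The sites of both proteins were spread over the chromosomes in a like way. Chromosome 19 was the densest, with 6.65 bio-zfp148 sites per Mb (6.01 to 7.34) and 5.01 bio-zfp281 sites per Mb (4.45 to 5.61). Chromosome 17 followed with 3.70 (3.29 to 4.14) and 2.77 (2.42 to 3.16). Chromosome 13 held 0.687 and 0.426 sites per Mb, and the X chromosome 0.659 and 0.446. No difference between the proteins in a chromosome's share of sites was detected by Fisher's exact test adjusted over 23 chromosomes (lowest adjusted p = 0.865, two-sided), in site sets that overlap and so are not independent. The lowest unadjusted p was 0.0706, for chromosome 12, which held 6.18% of bio-zfp148 and 5.23% of bio-zfp281 sites. Across the 23 chromosomes the densities of both proteins followed each other with r = 0.994 and rho = 0.991 (two-sided permutation p = 1e-05 for each, the smallest possible; adjusted 1.67e-05), and r = 0.972 without the 2 chromosomes farthest from the median. They also followed the density of BirA replicate 2 peaks, with r = 0.915 for bio-zfp148 and 0.944 for bio-zfp281 (rho 0.956 and 0.964; permutation p = 1e-05 each, adjusted 1.67e-05) and 0.942 and 0.960 without the farthest 2. Against the density of BirA replicate 1 peaks the relation was not detected, with r = 0.204 for bio-zfp148 and 0.200 for bio-zfp281 (permutation p = 0.348 and 0.358, adjusted 0.358 for both) and rho = 0.371 and 0.426 (p = 0.0825 and 0.0433, adjusted 0.0825 and 0.0541). The values without the farthest 2 were 0.149 and 0.141.

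**Figure D5:**
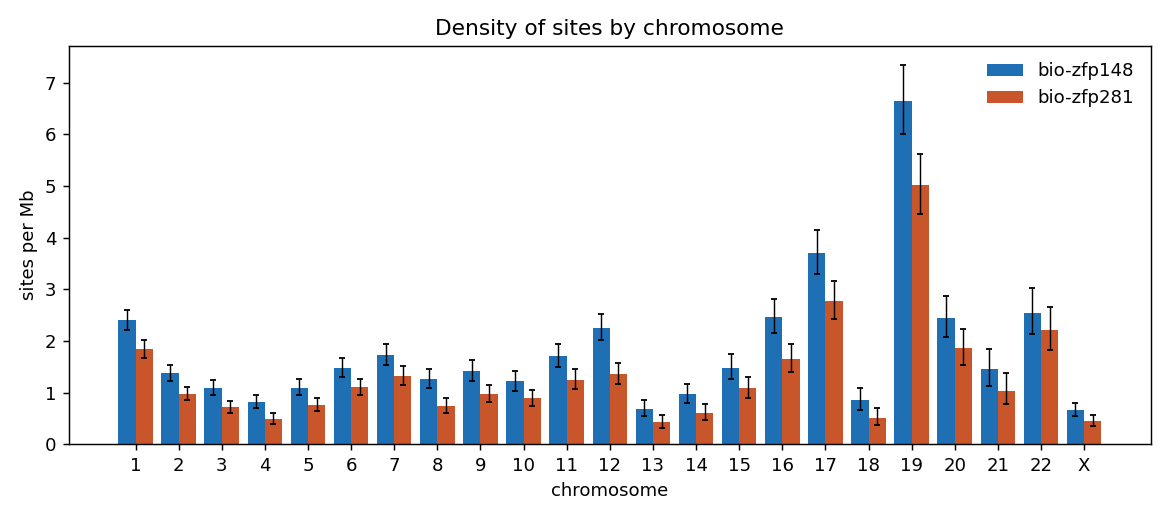
Sites per Mb on each chromosome for bio-zfp148 (blue) and bio-zfp281 (orange), with exact 95% Poisson intervals. Chromosome 19 held 6.65 and 5.01 sites per Mb, the highest of both proteins.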

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

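The alternative without chromosomes 9, 22, M and Y, the counts over any pooled peak of the other protein and the crossed block were chosen after seeing the data. All 73 alternative shares (of sites shared, of peaks met by BirA and of replicate overlap) stayed above the mean of 100 random placements. The one-sided permutation p was 0.01 for each, the smallest these can give. Mean placement shares were at most 3.44%, so this does not show that the shares were stable. The share changed more than 1.5-fold in 5 of 20 alternatives for bio-zfp148 sites and 2 of 20 for bio-zfp281 sites. It did so in 4 of 9 for bio-zfp148 and 5 of 9 for bio-zfp281 peaks met by BirA. For replicate overlap it did so in 3 of 5 for BirA and in none for the tagged proteins. Shared bio-zfp148 sites ranged from 14.3% to 89.0%, the latter against any pooled bio-zfp281 peak. Of 32 alternative site counts that could move, 19 stayed within 1.5 times the main count. A minimum fold enrichment of 10 left 2043 bio-zfp148 and 480 bio-zfp281 sites. No BirA removal gave 8520 and 7066, and removing only BirA peaks found in both replicates gave 7922 and 6397, since fewer peaks were then removed. With no replicate support the counts were 34019 and 52989. The other protein's replicates do not enter the definition of a site, so the 4885 bio-zfp148 and 3462 bio-zfp281 sites could not move without them. With each of the other 4 replicates left out in turn the counts ranged from 6245 to 12371 for bio-zfp148 and from 4771 to 19144 for bio-zfp281, the highest where 1 library's own peaks stood for the group. The minimum of 10 was applied to every list, although fold enrichment is scaled within each. It lay above the median of every single library of tagged protein, 5.05 and 6.39 in bio-zfp148 and 3.77 and 3.11 in bio-zfp281. Most of their peaks could thus no longer give replicate support, but how much of the fall this made was not tested. Replicate support rests on libraries of 810565 to 1570283 filtered tags, and how far this depth limits the sites was not compared with the other limits.

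A replicate block, in which each replicate was cleared of the same-numbered BirA library, gave 5288 bio-zfp148 and 3828 bio-zfp281 sites and shares of 42.0% and 57.5%. Crossed numbers gave 5275 and 3861 sites. The replicate 1 minus replicate 2 differences in log2 fold enrichment correlated at -0.20 between bio-zfp148 and bio-zfp281 over 3589 places, -0.05 between BirA and bio-zfp148 and -0.01 between BirA and bio-zfp281. The samples share only a number.

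The promoter, gene list and sequence element results, with their alternatives, were not run, because no hg19 genome or annotation was used.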

Other observations

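The counts of clusters, of sites absent from the other protein's lists, of crowded regions and over any pooled peak, the values without chromosomes 9, 22, M and Y, and the tests of whether BirA replicate 2 was a tagged library, carried tagged material or shared its background with BirA replicate 1, of whether its weakest calls recurred, and of depth with a minimum of 7 tags or by part of the sites, were chosen only after the result was seen.

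A few regions held several sites close together. With sites at most 5 kb apart joined, 27 clusters of at least 3 bio-zfp148 sites and 26 of bio-zfp281 sites were found, none with more than 5. The largest of bio-zfp148 spanned 12.6 kb at chromosome 12:54378165-54390784, held 5 sites, all shared, and met a bio-zfp281 cluster of 4 sites, all shared. Chromosome 16:85640456-85648153 held 4 bio-zfp148 sites, all shared, with a fold enrichment of up to 131. The largest bio-zfp281 cluster, at chromosome 22:19701755-19718954, held 5 sites, of which 1 was shared, with a fold enrichment of at most 18.4. A bio-zfp148 cluster of 4 sites at chromosome 12:112034848-112037492 had none shared and a fold enrichment of at most 15.2.

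Sites with no peak in any list of the other protein were a minority, 502 (10.3%, 9.44 to 11.2%) for bio-zfp148 and 420 (12.1%, 11.1 to 13.3%) for bio-zfp281. They were weaker than shared sites, with a median of 19 and 24 tags against 39 and 43, though above the median of 10 in both pooled lists. The strongest of bio-zfp148 lay at chromosome X:151902575-151902990, with a fold enrichment of 130 on 37 tags, and at chromosome 8:142710218-142710794, with 98.2 on 32 tags. For bio-zfp281 they lay at chromosome 20:61317454-61318196, with 135 on 51 tags, and chromosome 13:114880557-114881179, with 103 on 42 tags. Mitochondrial DNA gave a peak in all 3 bio-zfp148 lists (7817 tags in the pooled list, fold enrichment 2.68), counted as 1 site, and in none of the bio-zfp281 or BirA lists. At chromosome 22:22896908-22902501 the pooled lists held 3335 bio-zfp281 tags at a fold enrichment of 13.8 and 2933 bio-zfp148 tags at 17.3. The fold enrichment there was 7.82 and 8.33 in the single bio-zfp148 libraries, 6.84 and 5.78 in the single bio-zfp281 libraries and 2.36 in BirA replicate 2. The interval from 18 to 24 Mb of chromosome 22, 0.198% of the span, held 4.34% (3.89 to 4.81%) of BirA replicate 2 peaks and 2.94% of bio-zfp281 replicate 2 peaks but 0.353% of BirA replicate 1 peaks. The fold enrichment was under 1 at 1384 (4.80%) of bio-zfp281 replicate 1 peaks and 729 (7.37%) of replicate 2 peaks, at 441 (2.69%) of bio-zfp148 replicate 1 and 37 of replicate 2 peaks, at 187 (2.39%) of BirA replicate 2 peaks and at 4 pooled bio-zfp281 peaks.

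The strongest 10% of pooled peaks met a BirA peak in 48.8% of cases for bio-zfp148 and 50.4% for bio-zfp281, against 19.7% and 15.7% in the weakest 10%. Width was not the whole cause: strong peaks no wider than the median weak one still met BirA in 28.1% (24.6 to 31.8%) and 31.8% (29.0 to 34.8%) of cases, although less often than all strong peaks. Copies gained on chromosomes 9 and 22 in this line also left the pattern in place, since without chromosomes 9, 22, M and Y the shares were 49.1% and 50.6%. A background of the tag-free cells as such stays open. Of the highest 20% by fold of peaks found in both replicates, BirA replicate 1 called 12.0% and 18.3%, and BirA replicate 2 called 39.4% and 43.8%. However, the input was scaled up for BirA replicate 1 and the ChIP for BirA replicate 2, so their calls may not be comparable. Missing calls in BirA replicate 1 therefore do not show that a background was absent.

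BirA replicate 2 met bio-zfp281 replicate 1 in 53.9% of its peaks and BirA replicate 1 in 24.1%. Weak calls in replicate 2 that no other library repeats were argued against. Even its weakest 20% by p met a peak of a tagged library in 61.7% (59.2 to 64.1%) of cases, against at most 3.58% in 100 random placements. Other shares did rise with strength. From its weakest to its strongest 20%, 14.9% and 27.8% met BirA replicate 1, and 19.2% and 63.7% met the pooled BirA list, which includes its tags. The shares in BirA replicate 1 say little, because its peaks were called with the input scaled up and may not be comparable with those of replicate 2. A tagged library of like enrichment under a wrong label was argued against: of the highest 20% by fold of bio-zfp148 peaks found in both replicates BirA replicate 2 called 39.4%, where the shallower bio-zfp281 replicate 2 called 73.8%, and of bio-zfp281 peaks 43.8%, where the shallower bio-zfp148 replicate 1 called 87.8%. Carry-over of some tagged material stays open, since outside chromosomes 9, 22, M and Y BirA replicate 2 called the highest 20% by fold more often than the lowest, 39.6% against 24.7% for bio-zfp148 (19.0% in the next 20%, so not a steady rise) and 44.0% against 26.0% for bio-zfp281. Chromatin that any streptavidin pulldown recovers could give the same order in that library, and no biological explanation was tested.

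While 89.0% of bio-zfp148 sites met a pooled bio-zfp281 peak, 41.3% met a bio-zfp281 site. Whether the depth of bio-zfp281 replicate 2 alone was the whole cause could not be decided. Of 3817 bio-zfp148 sites called in bio-zfp281 replicate 1, replicate 2 called 54.4% (52.8 to 56.0%). From the replicate 1 tags at the lower depth, 72.9% was expected with a minimum of 5 tags, the fewest of any replicate 2 peak. With a minimum of 7 tags, the median of replicate 2 peaks, 56.0% was expected. Of the 40% of sites with most tags, 77.7% (75.6 to 79.8%) were called, against 94.4% expected with 7 tags and 98.7% with 5. Of the other 60%, 38.9% were called, against 30.4% expected with 7 tags and 55.7% with 5. With 7 tags the expected share was thus too high for the former sites and too low for the latter. The sites were selected for a replicate 1 call, which can raise the expected shares, and the same minimum was used everywhere. The comparison therefore draws no conclusion on depth, and a lower enrichment in that replicate also stays open. The hypothesis that the proteins occupy different places predicted closer overlap within than between proteins. It was tested among the strongest 5000 peaks of each library outside BirA peaks. There, bio-zfp148 replicate 2 met bio-zfp281 replicate 1 in 46.8% of cases. The replicates met each other in 46.7% for bio-zfp148 and 42.2% for bio-zfp281. However, the first pair joined the tagged libraries with most filtered tags, 1497503 and 1570283, whereas each replicate pair joined a deeper and a shallower library. Pairs of different proteins that also joined a deeper and a shallower library gave 39.0% and 39.4%, under both replicate pairs. The pair of shallower libraries gave 35.1%. Because depth differed between the pairs, the highest value does not decide the question.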
